A study of Mus musculus with 8 samples.

How the data were processed

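RNA of primary mouse articular chondrocytes was sequenced after transfection with a miR-204 mimic or with a control small RNA (miR-Ctrl), in 4 libraries per group. Per the labels' protocols, the libraries were stranded and made from polyadenylated RNA. The deposited table held 1 FPKM value (fragments scaled to transcript length and to the number of mapped fragments) per gene and library. The submitters' processing notes name TopHat, whose version is not given in the sources used here, Cufflinks 2.2.1 and the mouse build mm10. The Cufflinks mode and any filter are not given in the sources used here. FPKM values are not read counts, so no count model was used. A gene's FPKM falls when a few other genes take more of the fragments, and reads shared by near-identical genes can be split between them by an unknown rule.

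The table had 24067 genes, each with a different Entrez identifier. A total of 27 gene symbols had been turned into calendar dates and 131 were missing. Of these, 156 symbols were restored through the Entrez identifier and 2 were not. Of all identifiers, 23987 were found in the reference table of gene names. No symbol was repeated, so the planned test of repeated entries on their own did not apply. Gene positions and 3′ UTRs came from the GENCODE mouse release M21 annotation, which uses the same assembly as mm10. A 3′ UTR was found for 19960 genes. The deposited table lists RefSeq transcripts for each gene, whose models were not used here, so the 3′ UTRs searched may differ from those behind the FPKM values.

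FPKM summed to between 416560 and 490818 per library. Read totals are not given, but steps between low FPKM values gave the depth relative to miR-Ctrl replicate 1. It was 0.772 in miR-Ctrl replicate 2 and 0.798 in miR-204 replicate 2, and between 0.929 and 0.962 in the other 5 libraries. The lower depth of both replicate 2 libraries makes their low values less precise.

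Groups and replicate numbers came from the labels. The tests, the gene lists and the rule for named genes were fixed before the data were examined. Genes with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior, no minimum fold and Benjamini-Hochberg adjustment at 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale and understate changes of low genes. Adjusted p-values below are from limma with this adjustment. Nothing in the labels says that the replicates are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

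The main test left out the replicate number, and a fit with the number as a block was chosen as the alternative to it. The number paired the samples. Deviations from the group means correlated between libraries of equal number with r = 0.44, 0.82, 0.76 and 0.62 for replicates 1 to 4, across genes, and each of the 8 libraries correlated best with the library of its own number. The pairing thus comes from the data, since the labels give only the number. The paired result is given beside the unpaired one where it changed a call or moved a count by more than 1.5 times.

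The 29 gene lists covered cartilage and proteoglycan synthesis, signalling, stress responses and markers of other cell types. They were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. A list needed 3 tested genes, which 28 lists had. Erythroid markers were too low to test, with Hba-a1 at no more than 0.330 FPKM in any library.

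Sites of miR-204-5p (UUCCCUUUGUCAUCCUAUGCCU) were searched in the longest annotated 3′ UTR of each gene as 8mer AAAGGGAA, 7mer-m8 AAAGGGA, 7mer-A1 AAGGGAA and 6mer AAGGGA. Per library, the median of gene-centred log2 values over genes with a 7mer or 8mer was set against that over genes with no site, and the groups were compared with an exact two-sided permutation test of the 8 libraries, which has 70 assignments. The 6mer-only genes were in neither set. All 7-base words found in the 3′ UTRs of at least 50 tested genes were ranked by a Wilcoxon z of the fold changes of genes with against without the word.

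The named genes were those with the 12 largest rises and falls among genes past the threshold without overlap between groups, and up to 4 passing members of each list or, where none passed, the 2 with the highest mean. Acan, Col2a1, Sox9, Hapln1, Slc35d1, Mmp13, Cdkn1a and Trpm3 were always named, as were the 6 largest falls among called genes with an 8mer. The same rule was applied to the paired fit for the further genes named from it, without the condition on overlap, and this was chosen after their values were seen. Some genes that the rule or a list would name are not reported here.

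On simulated data of 11612 genes for this comparison, the unpaired test recovered 61% of genes changed 1.5-fold and 83% of those changed 2-fold. It called 0 unchanged genes. The simulated libraries kept the pair effects of the real ones, which the unpaired test counts as noise. The 0 may thus reflect a test made strict by the ignored pairing. The paired test recovered 88% and 99%, and 3.11% of its calls were unchanged genes. The simulated noise was independent between genes, no general shift between groups was simulated, and the least abundant genes were not among those changed. These rates need not hold for such genes or for the real paired calls, where the median log2 fold change of all genes was 0.064. A simulated log2 shift of −0.15 of the site genes was estimated as −0.1498 in 9721 genes. Alternatives were other pseudocounts, filters, scalings, fold and p thresholds, the replicate block, and leaving out each library. Alternatives of the paired fit, the removal of both libraries of a replicate number, and single site classes were added after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.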

Results

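The data came from chondrocytes, the cells that make and maintain cartilage, cultured from the knee cartilage of 5-day-old ICR mice. The cells received 50 nM of a mimic of miR-204, a small RNA that lowers transcripts carrying a match to its seed, or of a control small RNA. Transfection lasted 24 h and cells were harvested 24 h later. There were 4 libraries per group, and between 11184 and 11647 genes reached 1 FPKM in a library. Col2a1, which encodes the main collagen of cartilage, held the largest part of the summed FPKM in 6 libraries (3.71% to 6.36%). Saa3, an acute-phase protein gene, did so in both replicate 2 libraries (5.42% with miR-Ctrl and 3.40% with miR-204).

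The libraries were ordered mainly by replicate number. The first principal component held 58.4% of the variance and set both replicate 2 libraries apart from the other 6. Mmp13, a collagen-degrading protease, was at 1628 FPKM in miR-Ctrl replicate 2 and at 908 in miR-204 replicate 2, against 3.66 to 54.8 in the other 6 libraries. Acan, which encodes the aggrecan core protein, was at 386 and 407 FPKM there and between 959 and 1710 elsewhere. Libraries of equal number correlated at r = 0.986 to 0.989 over 11612 genes, and the lowest correlation within a group was 0.931.

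**Figure D1:**
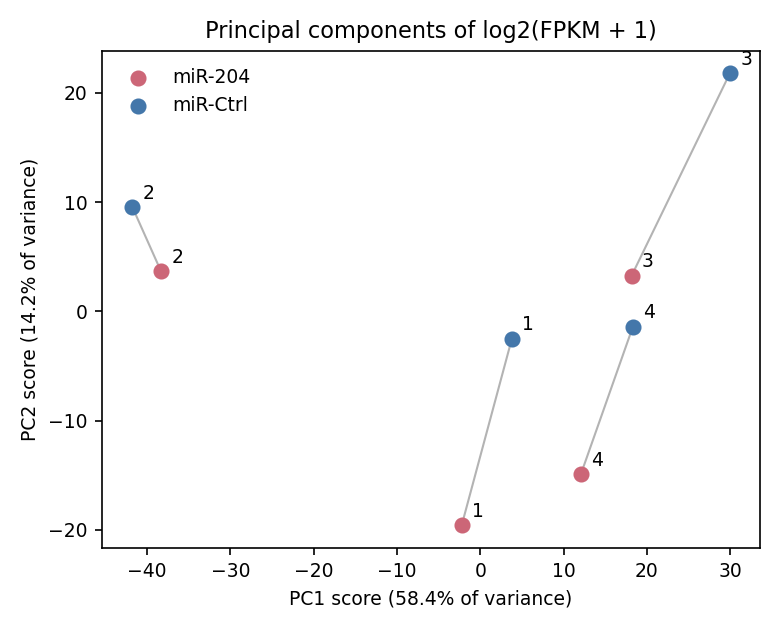
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis; points are libraries, numbers are replicates and grey lines join equal numbers. Both replicate 2 libraries lie at scores of −41.8 and −38.3 on the first component, and the other 6 lie between −2.23 and 29.96.

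The first question was which transcripts differed after the miR-204 mimic. Mlec (gene ID 109154), which encodes a carbohydrate-binding protein of the endoplasmic reticulum, fell from 70.1 ± 1.08 to 38.0 ± 0.793 FPKM (mean ± SD, n = 4), with a log2 fold change of −0.87 ± 0.045 (SE) and an adjusted p of 5.07e-04. Ak4 (11639), a mitochondrial adenylate kinase, fell from 13.5 ± 3.92 to 4.69 ± 0.545 FPKM (log2 fold change −1.32, adjusted p = 0.0310). The zinc transporter gene Slc39a11 (69806) fell from 24.5 ± 3.01 to 9.80 ± 1.34 FPKM (−1.24, adjusted p = 0.0142). Rab22a (19334), a small GTPase of endosomes, fell from 18.7 ± 1.82 to 9.36 ± 0.902 FPKM (−0.93, adjusted p = 0.0143). Acta2 (11475), smooth muscle actin, rose from 92.0 ± 7.74 to 187 ± 29.7 FPKM (log2 fold change 1.01, adjusted p = 0.0242).

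In all, 3 of 11612 tested genes were higher and 21 lower with miR-204. Each of the 24 moved one way in all 4 pairs of equal number, without overlap between the groups. The test that chose them favours such genes, so this adds no support. Of all tested genes, 41.3% moved one way in all 4 pairs. Groups did not overlap in 685 genes (5.90%). Chance would give 2.86% if the 8 libraries were independent of each other. The replicate numbers paired them, so the 2.86% is not a fitting reference here. Other large falls were Cmtm6 (−0.97), Ankrd13a (−0.85), the transcription factor gene Klf2 (−0.78), Eef1e1 (−0.73), Marchf3 (−0.71), 3110043O21Rik (−0.71) and Mmgt1 (−0.68). The other rises were Gsta1 (14857), from 1.99 ± 0.661 to 6.37 ± 1.08 FPKM (1.31), and Gm3776 (100042295), from 1.53 ± 0.427 to 4.70 ± 0.833 FPKM (1.17). Gsta1 and Gm3776 are neighbours on chromosome 9 in the glutathione S-transferase alpha family, and how reads were shared between them is not known. With the replicate block, 1436 genes were higher and 329 lower, and these included all 24. At a minimum of 1.5-fold the paired counts were 67 and 29. Higher genes made up 81.4% of the paired calls, against 55.7% with libraries centred on their median (603 higher, 479 lower) and 50.9% with quantile normalization (555 and 536). The median log2 fold change of all genes was 0.064. Without both libraries of replicate 1, 2, 3 or 4 the paired counts were 137 higher and 93 lower, 2828 and 535, 264 and 153, and 88 and 82. The unpaired counts were then 0 and 0 by limma (412 and 151 at an unadjusted p under 0.05), 2 and 16, 0 and 0 (433 and 190), and 0 and 0 (374 and 147).

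Leaving out a single library lowered the unpaired count of lower genes to 1 without miR-Ctrl replicate 1, to 7 without miR-Ctrl replicate 3 and to 2 without miR-Ctrl replicate 4. It was 2, 8, 1 and 1 without miR-204 replicates 1, 2, 3 and 4, and in all of these fits the count of higher genes was 0 by limma, with between 484 and 712 higher genes at an unadjusted p under 0.05.

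**Figure D2:**
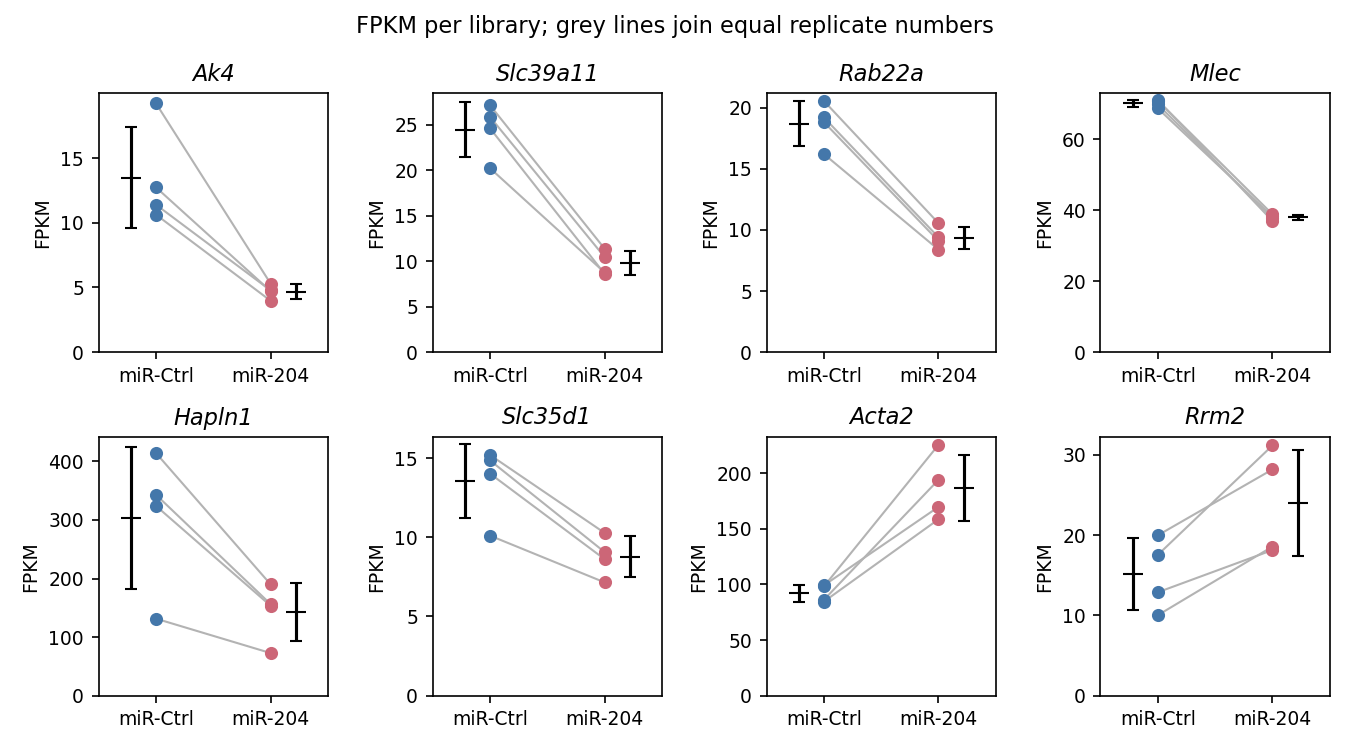
FPKM of 8 genes in each library (points), with grey lines joining equal replicate numbers and black bars showing mean and SD of the 4 libraries of a group; axes start at 0. Hapln1 and Rrm2 moved the same way in all 4 pairs while their groups were spread widely, and Mlec had an SD of 1.08 FPKM or less in both groups.

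The second question was whether the falls lay in genes with a match to the miR-204-5p seed. They did so in 19 of the 21 lower genes, of which 14 had an 8mer. The 2 lower genes without a 7mer or 8mer were Klf2, with a 6mer, and Marchf3, with no site. None of the 3 higher genes had a 7mer or 8mer, but only 2670 of 11181 tested genes with a 3′ UTR had one. These 3 genes are too few for a contrast, and the neighbours Gsta1 and Gm3776 have 3′ UTRs of only 106 and 105 nucleotides. Genes with a 7mer or 8mer (2670 genes) lay lower than site-free genes (7081) by 0.064 on the log2 scale, with medians of −0.033 ± 0.022 in the miR-204 libraries and 0.031 ± 0.021 in the miR-Ctrl libraries (SD, n = 4 each). The exact permutation p was 0.0286, the smallest that 4 against 4 libraries can give. The shift was −0.063, −0.049, −0.072 and −0.072 within pairs 1 to 4; a paired exact test cannot go below p = 0.125, which was its value.

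Genes with an 8mer shifted by −0.11 (exact p = 0.0286) and genes whose best site was a 7mer-m8 by −0.058 (exact p = 0.0286), while a 7mer-A1 gave −0.034 (exact p = 0.0571) and a 6mer −0.016 (exact p = 0.0857). In the paired fit 17.7% of 8mer genes were lower, 6.65% of 7mer-m8 genes, 4.21% of 7mer-A1 genes, 1.33% of 6mer genes and 0.904% of site-free genes. Higher in that fit were 4.12%, 9.78%, 10.9%, 12.7% and 14.1% of these classes. With centred libraries 22.2%, 9.27%, 5.99%, 2.52% and 1.58% were lower and 1.68%, 3.33%, 3.66%, 4.76% and 6.24% higher. Across genes, which are not independent replicates, 19 of 2670 site genes and 1 of 7081 site-free genes were lower unpaired (Fisher's exact p = 2.90e-10, two-sided). Fisher's exact test of the paired calls gave an odds ratio of 10.9 for genes with a 7mer or 8mer against site-free genes (241 of 2670 and 64 of 7081, p = 3.06e-81). Among 16093 words of 7 bases, the match AAAGGGA ranked 1 and AAGGGAA ranked 2 for lower fold changes (z = −20.8 and −18.5).

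**Figure D3:**
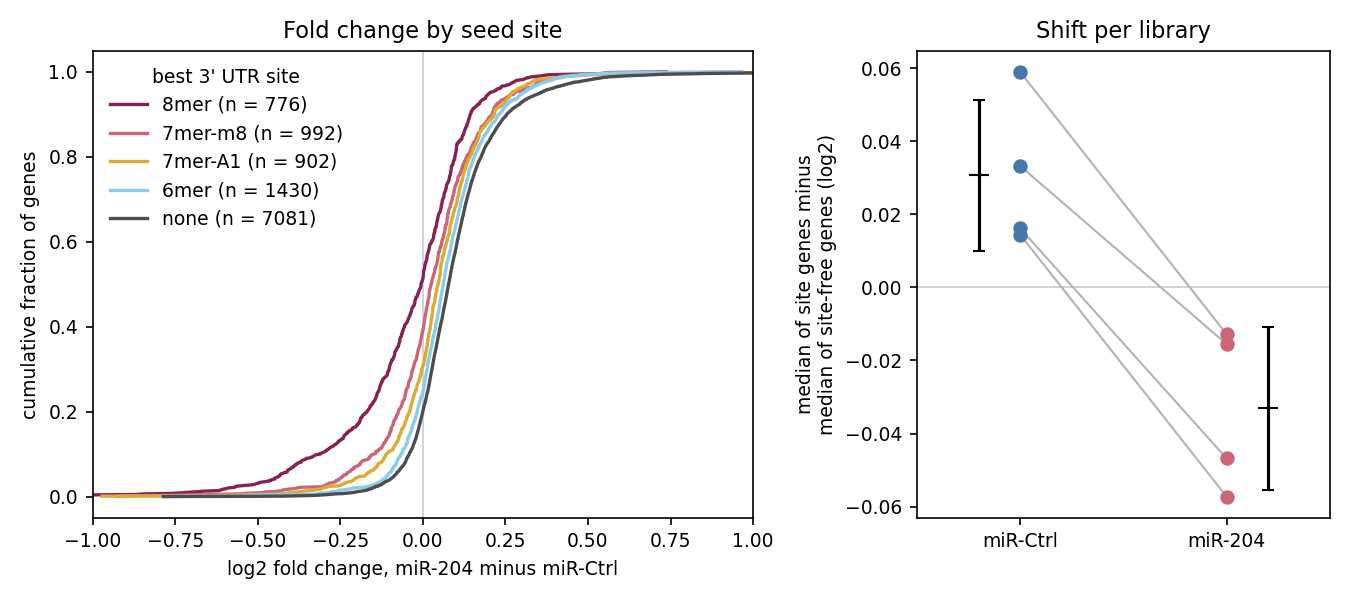
Left, cumulative fraction of genes against log2 fold change (miR-204 minus miR-Ctrl) by the best site in the 3′ UTR. Right, median of genes with a 7mer or 8mer minus median of site-free genes in each library (log2), with mean and SD in black and grey lines joining equal replicate numbers; the 4 miR-204 libraries lie between −0.057 and −0.013 and the 4 miR-Ctrl libraries between 0.014 and 0.059.

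The sites of the genes with the largest falls lay within single exons of 3′ UTRs (mm10, 1-based). The 8mer of Ak4 was on chromosome 4 at 101466576 to 101466583, in the gene at 101419277 to 101466995 on the plus strand, beside 4 further 7mers. Slc39a11 (chromosome 11, 113244853 to 113650079, minus strand) had its 8mer at 113244866 to 113244873. Mlec (chromosome 5, 115142981 to 115158179, minus strand) had its 8mer at 115145676 to 115145683. Rab22a (chromosome 2, 173659760 to 173707343, plus strand) had no 8mer but a 7mer-m8 at 173701309 to 173701315. The 8mers of Ankrd13a, Eef1e1 and Mmgt1 lay at 114805361 on chromosome 5, 38645750 on chromosome 13 and 56587924 on chromosome X.

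**Figure D4:**
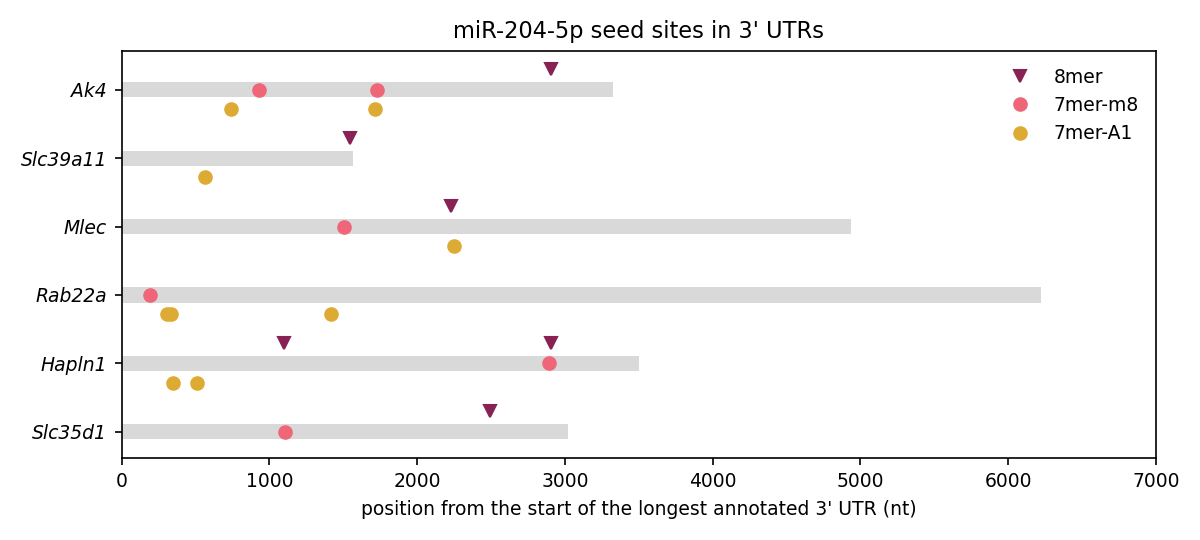
Maps to scale of the longest annotated 3′ UTRs of 6 genes, in nucleotides from the UTR start, with 8mer sites as triangles and 7mer sites as circles. Hapln1 has 2 8mer sites, and Ak4, Slc39a11, Mlec and Slc35d1 have 1 each.

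The third question was how genes of cartilage matrix and proteoglycan synthesis stood, the subject of the study's publication, so these lists are not independent of these samples. Hapln1 (gene ID 12950), the link protein that fastens aggrecan to hyaluronan, was at 303 ± 121 FPKM with miR-Ctrl and 143 ± 49.8 with miR-204 (log2 fold change −1.04). It did not pass the unpaired test (adjusted p = 0.531) but fell in the paired fit (adjusted p = 0.00136), in 4 of 4 pairs. Its 8mers lay on chromosome 13 at 89609247 to 89609254 and at 89611053 to 89611060. Slc35d1, a nucleotide sugar transporter needed for chondroitin sulfate, was at 13.5 ± 2.35 and 8.78 ± 1.29 FPKM (−0.57, adjusted p = 0.255, paired 0.00372). Its 8mer was on chromosome 4 at 103171171 to 103171178. Col2a1 (−0.23), Acan (−0.28) and the cartilage regulator Sox9 (−0.12) passed neither test, with paired adjusted p-values of 0.0594, 0.0773 and 0.0599. Col2a1 was at 0.12 under quantile normalization, which gives the most abundant gene of every library the same value. Col2a1 was that gene in both libraries of replicates 1, 3 and 4, so the 0.12 rests on pair 2 alone. Without this normalization its change in pair 2 was −0.068. Sox9, at −0.18 with centred libraries, passed the paired test with them (adjusted p = 0.0221).

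Of 23 cartilage matrix genes, 0 passed the unpaired test, also when adjusted over the list alone; Lect1, beside Col2a1 of highest mean, was at −0.028. In the paired fit, whose further genes were chosen after their values were seen, Hapln1, Col27a1 (−0.36) and Comp (−0.17) fell while Chad (0.54), Ucma (0.34) and Cilp2 (0.32) rose; with centred libraries Cilp2 did not pass. For sulfate and nucleotide sugar supply, 0 of 16 members passed unpaired, 2 were lower adjusted over the list alone, and the list lay lower than other genes (camera adjusted p = 0.00604, but adjusted p = 0.525 with an estimated correlation). Papss2 (−0.13) and Ugp2 (−0.020), of highest mean, did not pass. In the paired fit Slc35d1, Slc35d2 (−0.57), the sulfate transporter gene Slc26a2 (−0.22) and Impad1 (−0.21) fell, and 2 members rose, Slc35b3 (0.20) among them; with centred libraries 4 fell and 0 rose. The median of the list was −0.030. The list's call was lost without miR-Ctrl replicate 3 (adjusted p = 0.141) and without miR-204 replicate 2 (adjusted p = 0.243). Among 20 chondroitin sulfate chain genes, 0 passed unpaired and 1 was higher adjusted over the list alone; Xylt1 (−0.13) and Chst11 (−0.095) did not pass. The paired fit had Chst7 (0.25), B4galt7 (0.24) and Chpf2 (0.22) higher and Chsy1 (−0.21) lower, but with centred libraries Chst7 and B4galt7 did not pass, and 1 gene was higher and 2 lower. The list was not called (adjusted p = 0.618 unpaired and 0.318 paired). Of 13 heparan sulfate genes, Extl2 (0.16) rose in the paired fit but did not pass with centred libraries, and Sulf2 (0.22) and Ext2 (0.052) passed neither test. Of 11 hypertrophy genes, 1 was lower adjusted over the list alone; Alpl (−0.71), a phosphatase of mineralizing cells, and Pth1r (−0.31) fell and Enpp1 (0.39) rose in the paired fit, and Spp1 (0.54) passed neither. Mmp13 (−0.20) passed neither test.

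Reported miR-204 targets, of which 16 had a 7mer or 8mer, lay lower as a list of 19 genes (camera adjusted p = 1.17e-09, but adjusted p = 0.337 with an estimated correlation). Unpaired, Rab22a fell, and 3 members were lower adjusted over the list alone. In the paired fit 8 fell and 0 rose, among them Rab22a, Tgfbr2 (−0.76), M6pr (−0.36) and Ntrk2 (−0.35); Runx2, a bone and cartilage regulator, was at −0.29. Tgfbr2, the type 2 receptor of TGF-beta, went from 74.4 ± 11.6 to 43.5 ± 6.56 FPKM. Of 13 small RNA silencing genes, 1 was higher and 1 lower adjusted over the list alone. Ago1, which encodes an Argonaute protein, fell (−0.59) and Tnrc6a (0.34) rose in the paired fit, and Ddx5 (0.088) and Ddx17 (0.061) passed neither. Cpox (−0.91), Penk (−0.75) and Rspo3 (−0.75) were among the largest paired falls outside the lists. Trpm3, whose intron holds the miR-204 gene, was below the filter at 0.0743 ± 0.0356 and 0.0491 ± 0.0101 FPKM.

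Genes of cell division rose together in the paired fit. All 34 cell cycle genes had fold changes above 0, with a median of 0.39, while 8609 of all 11612 tested genes lay above 0. Unpaired, 0 passed by limma (5 at an unadjusted p below 0.05), also adjusted over the list alone; paired, 27 rose and 0 fell (18 rose with centred libraries), and 31 rose adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose from 15.1 ± 4.48 to 24.0 ± 6.65 FPKM (0.64, paired adjusted p = 0.00761), and Cenpa (0.63), Ube2c (0.57), Birc5 (0.56) and Pcna (0.26) rose also; Ube2c and Pcna did not pass with centred libraries. The list was called by camera (adjusted p = 3.26e-05, but adjusted p = 0.931 with an estimated correlation). Without miR-Ctrl replicate 2 its adjusted p was 0.252.

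Of 19 p53 response genes, 0 passed unpaired and 1 was higher adjusted over the list alone; in the paired fit 11 rose (6 with centred libraries) and Trp53inp1 (−0.25) fell. Perp (0.83), Tnfrsf10b (0.47), Plk2 (0.37) and Eda2r (0.35) rose, whereas Cdkn1a, a cell cycle inhibitor, was at 165 ± 24.7 and 171 ± 8.10 FPKM and passed neither test (0.058), nor did Bax (0.13). The list's adjusted p was 0.00604, and adjusted p = 0.931 with an estimated correlation; it was 0.080 without miR-Ctrl replicate 1 and 0.0555 without miR-204 replicate 2. All 15 interferon response genes had fold changes above 0, as did 8609 of all 11612 tested genes. The list's median was 0.76, yet it was −0.23 in pair 2 and 0.95, 0.51 and 1.22 in pairs 1, 3 and 4. Unpaired, 0 passed, and in the paired fit Bst2 (1.24) and Cxcl10 (0.87) rose, of which Cxcl10 did not pass with centred libraries; Isg15, at 13.6 ± 12.8 and 38.6 ± 35.2 FPKM, passed neither. The list's adjusted p was 0.0189, and adjusted p = 0.931 with an estimated correlation; it was 0.141 and 0.121 without miR-Ctrl replicates 3 and 4, and 0.404 and 0.0847 without miR-204 replicates 1 and 4. Of 5 smooth muscle and pericyte genes, Acta2 rose unpaired and 2 adjusted over the list alone, and Mcam (0.82) and Tagln (0.55) rose in the paired fit. Myh11 (mean 0.103 FPKM), Rgs5 (0.209) and Notch3 (0.87) of this list were below the filter, so its tested genes need not stand for such cells. The list's adjusted p was 0.0189, adjusted p = 0.905 with an estimated correlation and 0.0614 with the block; it was 0.0648 and 0.326 without miR-Ctrl replicates 1 and 2.

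**Figure D5:**
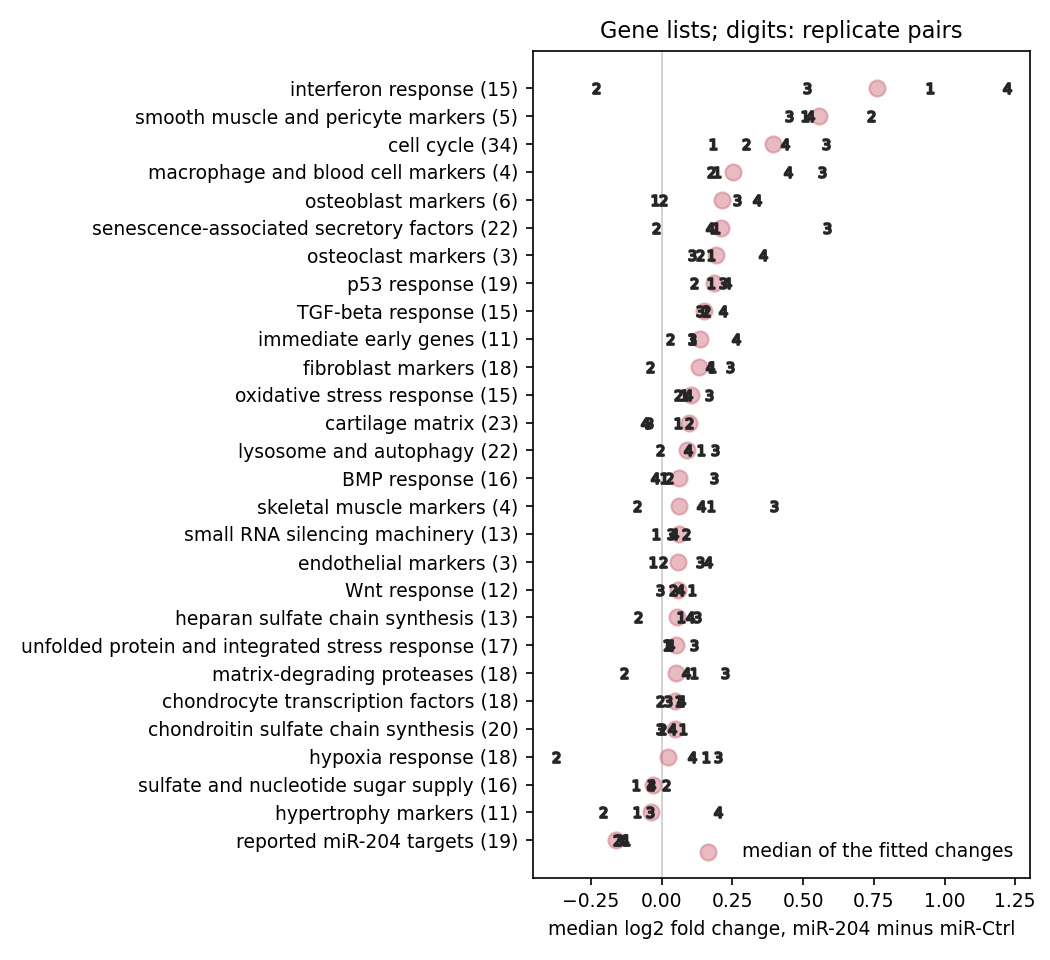
Median log2 fold change (miR-204 minus miR-Ctrl) of each gene list over its tested genes (number in brackets), as the median of the fitted changes (circles) and of each pair of equal replicate number (digits). The interferon list lies at 0.76 with pair 2 at −0.23, and the reported targets lie at −0.16.

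The other 22 lists, with all lists of cartilage and proteoglycans but sulfate supply among them, were not called (camera adjusted p between 0.395 and 0.994), and 0 of all 28 lists were called with an estimated correlation. Fry, which asks only whether a list moves one way on balance, gave unadjusted p = 0.259 for sulfate supply, 0.102 for p53, 0.140 for cell cycle, 0.191 for interferon, 0.0243 for reported targets and 0.00897 for smooth muscle and pericyte markers unpaired, and 0.0578, 0.00466, 0.0159, 0.0961, 0.00106 and 0.00747 paired. Fry does not set a list against other genes, so the median rise of all genes (0.064) enters its p-values. Paired, the other 22 lists had unadjusted fry p-values from 0.00517 (osteoclast markers, 3 genes) to 0.918 (small RNA silencing genes). Endothelial markers were at 0.0103 (3 genes), so a small fry p was not particular to the called lists. Of chondrocyte transcription factors, Foxa2 (−0.41) and Runx2 fell in the paired fit. Hif1a (0.048) did not pass. In the TGF-beta list Tgfbr2 was lower adjusted over the list alone; Tgfb3 (0.31), Klf10 (0.24) and Tgfb1 (0.20) rose paired, of which only Tgfb3 passed with centred libraries, and Ctgf (−0.037) and Tgfbi (0.0037) passed neither. In the BMP list Grem1 (0.52) and Bmp4 (0.23) rose and Nog (−0.32) fell paired, with Id3 (0.16) and Id1 (0.19) not passing. In the Wnt list Tcf7 (0.21) rose and Dkk3 (−0.32) and Wnt5a (−0.31) fell paired, where the rise of Tcf7 was lost with centred libraries, with Frzb (0.022) and Sfrp2 (0.22) not passing. Of the matrix-degrading proteases Plau (0.51), Plat (0.42) and Ctsk (0.25) rose and Adamts5 (−0.40) fell paired (2 higher, without Ctsk, and 2 lower with centred libraries), with Mmp3 (0.83) not passing. Of the senescence-associated secretory factors Ccl5 (0.97), Ccl2 (0.72), Ccl20 (0.50), Icam1 (0.49), Ereg (0.45) and Cxcl2 (0.43) rose and Pappa (−0.36) fell paired (4 higher, without Ccl20 and Cxcl2, and 1 lower with centred libraries), with Igfbp7 (0.056) and Mif (0.083) not passing.

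In the paired fit, hypoxia genes Car12 (0.30) and Pfkfb4 (0.24) rose, but neither passed with centred libraries, where 1 other gene was lower, with Eno1 (−0.093) and Aldoa (0.043) not passing. Of the unfolded protein response genes Dnajb9 (0.24) rose and Trib3 (−0.15) fell, where the rise was lost with centred libraries, with Hspa5 (−0.018) and Atf4 (0.051) not passing. Hmox1 (0.26) and Srxn1 (0.18) of the oxidative stress list rose, but neither passed with centred libraries, with Mt2 (0.22) and Mt1 (0.28) not passing. Lamp2 (0.23), Ulk1 (0.21), Sqstm1 (0.20) and Neu1 (0.19) of the lysosome list rose and Lamp1 (−0.28) fell, with Ctsd (0.16) not passing. With centred libraries 1 of this list, Lamp2, was higher and 3 were lower. Egr1 (0.46) and Fos (0.37) of the immediate early genes rose, with Jund (−0.087) and Ier3 (0.090) not passing.

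Beside Acta2, 0 markers of other cell types passed the unpaired test by limma. Among fibroblast markers Dpt (0.69), Col6a3 (0.44) and Thy1 (0.42) rose and Col5a1 (−0.34) fell in the paired fit, whereas Col1a1 (0.013) and Col1a2 (−0.053), the most abundant of them, passed neither test. Cd68, a macrophage marker, was at 1.511 ± 0.759 and 3.93 ± 0.979 FPKM and rose in the paired fit (1.01), and in the unpaired test it was higher adjusted over the list alone, while Lyz2 (0.45) and Laptm5 (0.050) passed neither. Only 4 of the 17 macrophage and blood cell markers were tested, and Ptprc (mean 0.0109 FPKM), Csf1r (0.111) and C1qa (0.14) were below the filter. Tested were also only 3 of 8 osteoclast, 4 of 12 skeletal muscle and 3 of 12 endothelial markers. Acp5 (0.56) of the osteoclast list and Acta1 (0.94) of the skeletal muscle list rose paired, with Mmp9 (0.027) and Tnni2 (0.012) not passing. Osteoblast markers Omd (0.0041) and Dlx5 (−0.0015) and endothelial markers Eng (0.21) and Erg (0.059) passed neither test.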

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

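The tests of other splits of the libraries were chosen only after the result was seen. Of 140 groups of 4 libraries tested for a library far from the other 3, 16 had one (11.4%, where chance gives about 5%), with 10 in miR-Ctrl replicate 2, 5 in miR-204 replicate 2 and 1 in miR-204 replicate 1.

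Among proteases, Mmp13 was at 1628 FPKM in miR-Ctrl replicate 2 and 908 in miR-204 replicate 2, Mmp3 at 1654 and 1262, and Mmp9 at 8.54 and 8.86, each far above the other 3 libraries of its group. Ier3, an immediate early gene, was at 91.7 FPKM in miR-Ctrl replicate 2 and 76.5 in miR-204 replicate 2. In miR-Ctrl replicate 2, Spp1 (1154 FPKM), Bax (179.7), Cmtm6 (9.78) and Marchf3 (6.28) lay above the other 3 libraries, and Sox9 (48.1) and Omd (12.6) lay below them. In miR-204 replicate 2, 3110043O21Rik was at 2.44 FPKM against 2.14 to 2.19 in the other 3. Ctsd, a lysosomal protease, was at 1829 FPKM in miR-204 replicate 1 against 1337 to 1417.

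Of the 35 splits of the 8 libraries into equal groups, 2 called at least as many genes without the block as the 24 of the real one, so chance cannot be excluded on this count. The highest other split called 123 genes; it sets replicates 1 and 2 against replicates 3 and 4 and so points to a structure of the samples by replicate number. Of the 8 splits that part all 4 pairs, 1 (the real one) called 24 genes and the highest other called 0. With the replicate block, 1 of these 8 called 1765 genes and the highest other 0. These 8 splits are too few for a share under 0.05.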

How the results depend on the processing

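Alternatives of the paired fit, removal of both libraries of a replicate number, single site classes and the repeats of the word ranks were chosen after seeing the data. Higher and lower counts without the block were 0 and 9 without a filter, 7 and 57 with centred libraries, 7 and 66 with quantile normalization, 3 and 2 at a minimum of 2-fold, 0 and 1 at an adjusted p of 0.01, and 1436 and 329 with the block; other settings stayed within 1.5 times. Where 0 genes were higher by limma, 1123 without a filter and 763 at the stricter threshold had an unadjusted p under 0.05. Without a single library they ranged from 0 to 4 and from 1 to 16, and all 24 genes kept their direction. With the block, counts were 542 and 197 without a filter, 603 and 479 centred, 555 and 536 with quantile normalization, 67 and 29 at 1.5-fold, 11 and 3 at 2-fold, and 128 and 101 at an adjusted p of 0.01. Without both libraries of a replicate number they ranged from 88 to 2828 and from 82 to 535 with the block, and from 0 to 2 and from 0 to 16 without it. Of the gene lists, 6 were called without and 5 with the block, and 0 with an estimated correlation. The block changed no call of a named gene or list other than those given with it.

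The seed-match shift was −0.037 for coding-sequence sites, −0.0038 for the miR-204-3p match, −0.034 for a 7mer-A1 and −0.016 for a 6mer as best site, each above an exact p of 0.05, and −0.064 with the block, where 0.125 is the smallest p. Without a single library it ranged from −0.071 to −0.056. AAAGGGA and AAGGGAA ranked 1 and 2 in each repeat without a library and in each pair alone.

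Of 897 values of 69 named genes under alternatives, 682 kept direction and side of the threshold, 93 lost and 8 gained the call, and 114 reversed; 14 of 15 genes past the threshold lost it on leaving out at least 1 library. Log2 fold changes that reversed belonged to genes not called without the block. With centred libraries they were Aldoa −0.016, Atf4 −0.0081, Cdkn1a −0.0010, Col1a1 −0.046, Ext2 −0.0069, Frzb −0.037, Hif1a −0.011, Igfbp7 −0.0030, Laptm5 −0.0087, Mmp9 −0.032, Omd −0.055, Tgfbi −0.055 and Tnni2 −0.047. With quantile normalization they were Cdkn1a −0.0067, Col1a1 −0.037, Col2a1 0.12, Ddx17 −0.0056, Erg −0.016, Ext2 −0.0087, Frzb −0.044, Hif1a −0.032, Laptm5 −0.018, Mmp9 −0.017, Omd −0.062, Tgfbi −0.075 and Tnni2 −0.079. A pseudocount of 0.1 gave Tnni2 −0.040 and one of 5 gave Tgfbi −0.0018. Without a single library the ranges were Acan −0.77 to 0.087, Aldoa −0.024 to 0.17, Atf4 −0.046 to 0.13, Cdkn1a −0.0047 to 0.14, Chst11 −0.24 to 0.063, Col1a1 −0.17 to 0.21, Col1a2 −0.25 to 0.14, Col2a1 −0.57 to 0.068, Ctgf −0.18 to 0.20, Dlx5 −0.066 to 0.096, Eno1 −0.18 to 0.064, Erg −0.21 to 0.33, Ext2 −0.013 to 0.11, Frzb −0.19 to 0.21, Hif1a −0.12 to 0.24, Hspa5 −0.058 to 0.024, Id3 −0.30 to 0.40, Ier3 −0.49 to 0.78, Igfbp7 −0.061 to 0.16, Laptm5 −0.13 to 0.25, Lect1 −0.18 to 0.085, Mif −0.066 to 0.33, Mmp13 −1.66 to 1.48, Mmp3 −0.64 to 2.70, Mmp9 −0.72 to 0.77, Mt2 −0.21 to 0.76, Omd −0.23 to 0.20, Papss2 −0.44 to 0.087, Sfrp2 −0.48 to 0.79, Tgfbi −0.41 to 0.20, Tnni2 −0.29 to 0.21 and Ugp2 −0.065 to 0.039. The causes were not tested, but the 0.12 of Col2a1 under quantile normalization rests on pair 2 alone. In the other pairs Col2a1 was the most abundant gene of both libraries, and this normalization gives that gene the same value in every library. Low depth limits the precision of low genes, most in replicate 2, but Col2a1 and Acan were abundant. The fits without a single library had no block, so each left the other library of that number unmatched. Within pairs, Col2a1 was lower in 4 of 4 and Acan in 3 of 4.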

Other observations

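The tests of 3′ UTR length and GC content, of the 10 most abundant genes, of the cell cycle list and of site number were chosen only after the result was seen. For the 10 most abundant genes a first rule, on spreads over pairs, gave no verdict, and the rule on differences within pairs replaced it after the values of each pair were seen. The matched comparison and the miR-204-3p match were planned, but the bounds they are held to were set after their values were seen, and those for the least against the most abundant genes before that value but after the effect of centring was known. Both replicate 2 libraries stood apart with either small RNA in several genes, which were chosen after their values were seen and not tested as a group. The acute-phase gene Saa3 was at 26618 FPKM in miR-Ctrl replicate 2 and 16455 in miR-204 replicate 2, against 17.9 to 225 in the other 6 libraries. Lcn2, an iron-binding defence protein gene, was at 9134 and 5521 FPKM against 29.98 to 222, and the neutrophil-attracting chemokine gene Cxcl5 at 1069 and 974 FPKM against 0.413 to 23.3. Nos2 was at 21.2 and 20.6 FPKM there and at no more than 0.902 elsewhere. In the same libraries Col2a1 was at 8212 and 7836 FPKM against 16098 to 27530, and Comp at 758 and 685 FPKM against 1273 to 1927, while Ucma, of the same list, was at 589 and 814 FPKM against 591 to 1159. Nothing in the labels sets replicate 2 apart, and no explanation was tested.

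Several genes outside the lists, chosen after their values were seen, rose in the paired fit and not in the unpaired one. Sparcl1, a matrix protein gene, went from 6.59 ± 1.90 to 15.4 ± 4.42 FPKM (SD, n = 4; log2 fold change 1.11, paired limma adjusted p = 0.00202), and the protease inhibitor gene Spint2 from 12.3 ± 3.51 to 25.6 ± 3.46 FPKM (1.02, 0.00268). Cytl1 (1.33), Ifi27l2a (1.32), Gpnmb (1.08), Ptgds (0.98) and the small nucleolar RNA Snord15b (1.39) also rose, each in 4 of 4 pairs. Of all 11612 tested genes, 3933 did so in 4 of 4 pairs. Gpnmb did not pass with centred libraries.

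Genes with a seed site lay lower than site-free genes with miR-204. Against site-free genes matched on 3′ UTR length and expression the difference was −0.063 in 2274 pairs of genes (exact permutation p = 0.0286, two-sided, the smallest possible without pairing of libraries), which argues against these features as the cause. After length and GC content were regressed out, AAAGGGA still ranked 1 of 16093 words (z = −16.4), which argues against them too. An effect of the mimic through its seed stays open as a hypothesis consistent with these values.

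More genes were called higher than lower in the paired fit. Library scaling may account for it: the median rise of the least abundant genes, of 4 classes by mean FPKM of equal size, differed from that of the most abundant by −0.0031 ± 0.023 (SD over 4 pairs) among 7990 genes whose median rise was 0.065. The 10 genes of highest mean FPKM were taken as the most abundant, so longer genes that hold more fragments may be left out. A smaller share of fragments in these 10 genes predicted a rise of 0.033 ± 0.018, against 0.065 ± 0.024 observed (SD over 4 pairs). Within pairs the observed rise was above the predicted one by 0.032 ± 0.0061 (SD), in 4 of 4 pairs, which argues against this share as the whole cause; a part of the rise stays open. A general rise of transcripts with miR-204 was not tested apart from scaling.

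In the paired fit 27 of 34 cell cycle genes were called higher with miR-204, but 0 in the unpaired one by limma (5 at an unadjusted p below 0.05), and the paired list call was lost with an estimated correlation (adjusted p = 0.853). Centring the libraries left a median of 0.34, with 18 of 34 genes past the threshold, which argues against scaling as the whole cause. The lowest median of a pair was 0.18, so the rise was not that of a single pair. A lower share of chondrocytes could raise markers of all other cell types alike. Smooth muscle and pericyte markers moved more than fibroblast markers by 0.42 ± 0.25 (SD over 4 pairs). With 5 and 18 genes, and with Myh11, Rgs5 and Notch3 below the filter, this explanation cannot be told apart from an effect on division. More division with miR-204 stays a hypothesis.

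If several sites act together, genes with more sites could fall further. Genes with 2 or more 7mer or 8mer sites (712) lay lower than genes with 1 (1958), with a log2 difference of −0.045 (exact permutation p = 0.0286, two-sided, the smallest possible), without correction for UTR length. This permutation ignored the pairing, and a paired exact test cannot go below p = 0.125. The labels do not name the arm of the mimic. If a miR-204-3p strand acted as well, genes with a miR-204-3p match could fall. Their shift was −0.0038 (exact permutation p = 0.514, two-sided), which argues against a shift of that kind.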
